A study of Mus musculus with 71 samples.

How the data were processed

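The 6 tables list TPM for 55413 gene symbols, and the values of each column sum to 1e+06. Read counts and sequencing depth are not given in the sources used here, so no tool that needs counts was used. The submitters' notes name cutadapt 2.10, STAR 2.7.5c, RSEM 1.3.3, edgeR 3.32.0, Cell Ranger 7.0.0, Seurat 4.1.1 and R 4.1.3, with the builds GRCm38 and mm10. The TPM values were taken as deposited, and per the submitters they come from reads handled with cutadapt, STAR and RSEM, which estimates TPM. The settings of these tools are not given in the sources used here. Of the 71 samples, 67 bulk libraries were used, and the 4 hashed pools of single cells were not analysed here.

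Each table was analysed on its own with limma 3.58.1 in R 4.3.3. The values were log2(TPM + 1). A gene was tested when its TPM was at least 1 in as many libraries as the smallest group holds, which left 12877 genes for cuprizone, 14461 for glioma, 13513 for EAE, 12532 for 5xFAD, 13136 for the P6 stroke and 14303 for the P28 stroke. All 3 groups of a table entered 1 linear model, with moderated variances following a trend on the mean, and each contrast was adjusted over its tested genes by Benjamini and Hochberg. Genes with an adjusted p under 0.05 are the ones said to rise, to fall or to be called. Fold changes are differences of group means on the log2 scale with their standard error (SE), and levels are means with the standard deviation (SD) over libraries. The genes, groups, contrasts, gene lists, alternatives and the rule for naming genes were fixed before the data were examined, except for the alternatives said to be added.

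The named genes follow that rule. Spp1 is printed in every comparison because it is the gene behind the sorting gate. Per contrast of GFP-positive with GFP-negative libraries, the 8 genes with the largest positive and the 8 with the largest negative fold change are named, and per contrast with a reference group 6 and 6. They had an adjusted p under 0.05, a mean of at least 10 TPM in the higher group, and no overlap between the libraries of the 2 groups, so every library shows the direction of the group. A few genes that meet the rule are not reported here. Gene models without a given name, immunoglobulin and T cell receptor segments, Xist and the Y genes were left out. At most 6 members of a gene list are given as examples of it, by smallest adjusted p.

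The 34 gene lists were written down from general knowledge of the field. They cover disease-associated microglia, homeostatic microglia, the interferon response, MHC class II, MHC class I, chemokines and cytokines, NF-kB targets, the cell cycle, lipid uptake with efflux and storage, cholesterol synthesis, the lysosome, phagocytic receptors with complement, glycolysis, the hypoxia response, oxidative phosphorylation, remodelling of the extracellular matrix, growth factors, postnatal amoeboid microglia, immediate early and heat shock genes, the unfolded protein response, and iron with redox genes. A further 13 lists hold markers of other cells, namely monocyte-derived cells, border-associated macrophages, neutrophils, dendritic cells, T cells, NK cells, B cells, oligodendrocytes, oligodendrocyte precursors, astrocytes, neurons, endothelial cells with pericytes, and erythroid cells. Lists were tested with camera from limma at a preset correlation of 0.01 between genes, adjusted over the lists of a contrast. Repeats used fry and a correlation estimated from the data, printed mainly where a call was lost. A list with under 3 tested genes had no set test. Beside the called members of a list in a contrast stands the count after adjusting over the genes of that list alone.

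Genes shared by the 6 models were those tested in all 6 tables and called in the same direction in each. Differences between models were tested on 11301 genes tested in all tables, with an F test over the 6 contrasts of GFP-positive with GFP-negative libraries, and for the 2 strokes with the difference of their contrasts over 12413 genes. The 6 tables were normalised separately, so tests between tables used only contrasts inside a table, and no level was tested between tables. Permutation tests of list means used every split of the libraries of 2 groups.

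Positions are those of GENCODE release M21 on GRCm38, where 53292 of the symbols were found. Of the 656 genes in the lists, 1 (Ahsp) is not in the tables, and no table has an entry for the GFP transgene. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

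The fits were tried on simulated tables of independent genes with the real group sizes and spreads (100 genes changed 2-fold and 100 4-fold). Of the 2-fold changes the fit found 59 for cuprizone, 67 for glioma, 40 for EAE, 49 for 5xFAD, 80 for the P6 stroke and 78 for the P28 stroke, and of the 4-fold changes 90, 93, 81, 91, 99 and 97. Unchanged genes made up 3.61 to 8.33% of the calls. The F test over 6 models found 40 and 83, with 29.3% of its calls unchanged. A Welch test with the spread of each table, added for that reason after the data were seen, found 67 and 90 with 10.8% unchanged. The difference of the 2 strokes found 63 and 86 with 7.45% unchanged. With 28 genes raised 2-fold, camera called their list and 0 of 27 others, but correlated lists stay untested.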

Results

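Microglia from mice with a GFP reporter at Spp1, the gene for osteopontin, were sorted by GFP and sequenced as bulk libraries of 2000 cells in 6 disease models. The submitters ask how varied the reactive state of microglia is between disorders of the brain and whether it has a common signature. The models are a cuprizone diet of 5 weeks, which removes myelin (control 4, GFP-negative 3 and GFP-positive 3 libraries), and a CT2a glioma after 21 days (4, 4 and 4). EAE is an autoimmune inflammation, taken at clinical scores 1 to 2 (3, 3 and 3), and 5xFAD mice with amyloid were taken at 7 months (4, 4 and 4). Strokes were made at postnatal day 6 (P6) and day 28 (P28) and collected at day 9 and day 35 (4, 4 and 4 each). The reference of the strokes is the contralateral side of the same mice. In the 4 adult models the controls are wild type mice, so disease, reporter genotype and gate change together between a GFP group and its control. Expression is known as TPM only, and the depth of the libraries is not given in the sources used here. Means carry the SD over libraries, and the mean number of genes above 0 TPM ranged from 13700 in 5xFAD controls to 17527 in GFP-negative libraries of the glioma.

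Spp1, the gene of the gate, rose in GFP-positive cells of all 6 models. It averaged 698 ± 64.6 TPM in GFP-positive and 4.4 ± 2.21 TPM in GFP-negative libraries after cuprizone, 539 ± 302 and 57.1 ± 26.3 in glioma, and 969 ± 95.4 and 99.5 ± 34.7 in EAE. The same means were 766 ± 403 and 18.03 ± 5.49 in 5xFAD, 439 ± 242 and 29.8 ± 41.5 in the P6 stroke, and 1873 ± 1706 and 18.8 ± 17.7 in the P28 stroke. The log2 fold changes were 7.10 (SE 0.65, limma adjusted p = 2.56e-05), 3.15 (SE 0.70, 0.0198), and 3.33 (SE 0.39, 0.00532) in these 3 models. They were 5.22 (SE 0.80, 0.000761), 4.58 (SE 0.67, 0.00769) and 6.82 (SE 0.99, 0.000306) in 5xFAD and the strokes. GFP-negative libraries were above their reference for Spp1 in glioma (log2 fold change 3.43, SE 0.70, adjusted p = 0.00141) and EAE (1.53, SE 0.39, 0.0174). They were not called after cuprizone (0.28, SE 0.61, 0.949), in 5xFAD (2.25, SE 0.80, 0.0781), in the P6 stroke (1.11, SE 0.67, 0.754) or in the P28 stroke (1.70, SE 0.99, 0.692). GFP-positive libraries were above the reference by 7.38 (SE 0.61, 3.43e-06) after cuprizone, 6.58 (SE 0.70, 4.88e-06) in glioma and 4.86 (SE 0.39, 1.13e-05) in EAE. The same difference was 7.47 (SE 0.80, 3.58e-06) in 5xFAD, 5.68 (SE 0.67, 0.00112) in the P6 and 8.52 (SE 0.99, 2.76e-05) in the P28 stroke.

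**Figure D1:**
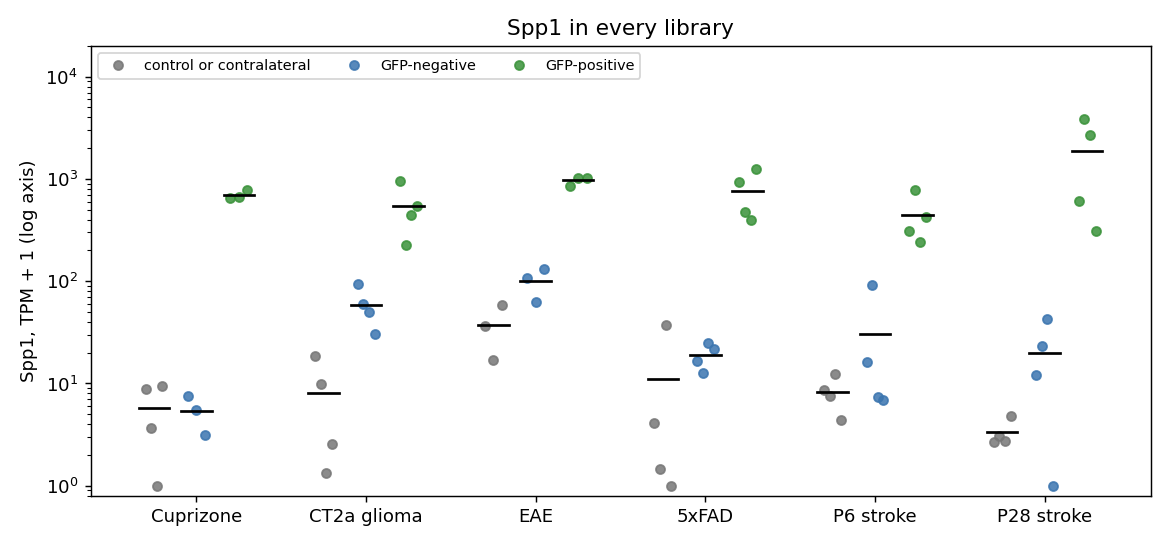
Spp1 in every library of the 6 models as TPM + 1 on a log axis, by group. In the P28 stroke the mean was 1873 TPM in GFP-positive and 18.8 TPM in GFP-negative libraries.

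After cuprizone, the comparison of GFP-positive with GFP-negative microglia (3 against 3 libraries) asks what marks reactive cells during demyelination. Apoe, which carries lipids, reached 105450 ± 4235 TPM against 6298 ± 1094 (log2 fold change 4.08, SE 0.13, adjusted p = 9.39e-10). Its neighbours in the same gene cluster rose with it, Apoc4 at 37.9 ± 16.6 against 0.0767 ± 0.133 TPM (5.10, SE 0.41, 1.07e-05) and Apoc1 at 74.5 ± 7.91 TPM where the GFP-negative libraries list 0 (adjusted p = 1.06e-05). The growth factor Igf1 (140.1 ± 14.7 against 4.84 ± 2.25 TPM, 4.65, SE 0.30, 1.6e-06) and the glycoprotein Gpnmb (25.2 ± 8.00 against 0.587 ± 0.590, 4.07, SE 0.46, 0.000122) rose. Actr3b of the actin machinery (4.42, SE 0.41, 2.53e-05) and the MHC class I gene H2-Q5 (4.18, SE 0.86, 0.00813) were higher as well. Of the 32 disease-associated microglia genes 28 rose and 0 fell (28 adjusted over the list alone, camera adjusted p = 1.32e-55). Among them were Lpl at 912 against 94.6 TPM (3.26, SE 0.50, 0.00121), Lgals3 at 457.5 against 72.1 (2.64, SE 0.25, 2.98e-05), Fabp5 at 38.4 against 1.37 and Lyz2 at 2428 against 682. The lists of amoeboid microglia (23 of 24 up, 23 alone, 1.7e-46), lipid handling (12 up and 2 down of 26, 14 and 3 alone, 2.48e-15) and the lysosome (13 up and 1 down of 31, 17 and 1 alone, 4.4e-16) rose. So did matrix remodelling (9 up of 19, 12 up and 2 down alone, 1.72e-14), glycolysis (9 up of 18, 10 up and 1 down alone, 9.73e-10) and MHC class II (4 up and 1 down of 12, 4 and 1 alone, 0.00275). The class II chaperone Cd74 was at 250.5 against 36.7 TPM (2.81, SE 0.31, 0.000104). Growth factors rose as a list too (3 of 13, 3 alone, 9.33e-06).

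Homeostatic microglia genes were lower in cuprizone GFP-positive cells, with 23 of 28 falling (27 alone, camera adjusted p = 2.1e-27), 18 of them after median-of-ratios rescaling. Tmem119 was 1365 against 5194 TPM (log2 fold change -1.94, SE 0.09, adjusted p = 5.24e-08) and the purine receptor P2ry12 2202 against 7751 (-1.83, SE 0.12, 2.35e-06). Falls were seen in the GTPase gene Gimap9 (0.587 ± 0.323 against 15.7 ± 8.09 TPM, -3.31, SE 0.40, 0.000176), Tmem44 (-2.91, SE 0.42, 0.000663) and the tetraspanin relative Upk1b (15.3 ± 4.47 against 100.1 ± 3.40, -2.66, SE 0.22, 1.14e-05). Next came Bank1 (-2.66, SE 0.38, 0.000661), Tmem204 (12.4 ± 5.27 against 78.7 ± 15.6, -2.63, SE 0.24, 2.73e-05), Layn (-2.53, SE 0.42, 0.00199), Enpp5 (-2.44, SE 0.56, 0.0141) and Tspan18 (-2.39, SE 0.38, 0.00142). The interferon response was called up (camera adjusted p = 0.00224) with 1 of 28 genes called (1 alone), Ifi204, and MHC class I with 2 of 16 (5 alone, 3.64e-05). Both calls were lost at adjusted p = 0.501 and adjusted p = 0.139 with an estimated correlation. For monocyte-derived cells the median of 13 genes was 0.00, the mean 0.70 and the test up (4 up and 1 down, 5 and 1 alone, 0.000264). In all 1313 of 12877 genes were called, 348 up and 965 down (26.5% up). After rescaling it was 538 and 245 (68.7% up), and before it the median of all genes was -0.25. Without GFP-negative library 1 the count was 823, without GFP-negative library 2 815, and without GFP-positive library 3 771.

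The GFP-negative microglia of the cuprizone mice differed from the controls (3 against 4 libraries) in 21 genes, 19 up and 2 down. Highest were the elastase Mmp12 (43.0 ± 12.4 against 2.13 ± 2.86 TPM, log2 fold change 4.27, SE 0.55, adjusted p = 0.00954) and the chemokine Ccl5 (40.6 ± 23.9 against 1.40 ± 1.61, 4.17, SE 0.63, 0.0234). The chemokines Ccl4 (120.2 ± 41.3 against 15.6 ± 12.8, 3.12, SE 0.43, 0.0118) and Ccl3 (232 ± 93.7 against 32.8 ± 5.49, 2.73, SE 0.21, 0.000107) rose too, and so did Lgals3 (72.1 ± 10.5 against 13.4 ± 4.24, 2.39, SE 0.23, 0.000816) and the kinase Fam20c (2.33, SE 0.33, 0.0161). Ms4a4a (-2.14, SE 0.38, 0.0485) and F13a1 (-1.86, SE 0.29, 0.0234) fell. Of the 32 disease-associated genes 8 rose (21 alone, camera adjusted p = 1.62e-27), and border-associated macrophage markers fell with 1 of 19 called (9 alone, 7.99e-10). Homeostatic genes had 0 of 28 called (2 down alone, 3.13e-06, adjusted p = 0.246 with an estimated correlation). The count was 12 without control 1, 9 without control 2, 3 without GFP-negative library 1 and 8 without GFP-negative library 2. The median of all genes was -0.03, and 1020 genes were at an unadjusted limma p under 0.05. By Xist and the Y genes, 2 of the 4 controls are female and the other cuprizone libraries male, and with a term for sex the count was 15 and with the replicate block 0.

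Against the controls, GFP-positive cuprizone microglia (3 against 4 libraries) showed Mmp12 at 266.7 ± 39.9 TPM (log2 fold change 6.90, SE 0.55, adjusted p = 2.54e-06) and Lpl at 912 ± 57.6 against 23.1 ± 17.8 (5.61, SE 0.47, 3.77e-06). Ch25h, which makes 25-hydroxycholesterol, was at 169.9 ± 19.7 against 4.10 ± 3.23 (5.30, SE 0.43, 2.54e-06), Apoc1 was higher (5.77, SE 0.46, 2.53e-06), and Apoc4 was listed at 0 in the controls. The lectin Cd209a (1.64 ± 2.14 against 38.2 ± 12.99, -4.15, SE 0.71, 0.00121), Ccdc162 (-3.89, SE 0.59, 0.000531) and Tmem204 (-3.46, SE 0.23, 5.04e-07) fell. Also lower were Mgl2 (-3.28, SE 0.50, 0.000579), Klrd1 (-3.19, SE 0.47, 0.000402) and Tmem44 (-3.08, SE 0.39, 0.000117). All told 2338 genes were called, 580 up and 1758 down (24.8% up). Rescaling changed this to 878 and 490 (64.2% up), and before it the median over all genes was -0.29. Without GFP-positive library 3 the count was 1555, and with the 2 male controls alone 1519.

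In glioma, GFP-positive and GFP-negative libraries (4 against 4) ask what separates Spp1-rich cells inside a tumour-bearing brain. The chemokine Ccl8 (160.3 ± 106 against 25.8 ± 11.8 TPM, log2 fold change 2.46, SE 0.47, adjusted p = 0.0102), Igf1 (37.0 ± 21.6 against 6.17 ± 4.42, 2.39, SE 0.51, 0.0167) and the scavenger receptor Colec12 (2.09, SE 0.51, 0.0292) rose. Ch25h (299.8 ± 18.6 against 84.6 ± 38.8, 1.97, SE 0.45, 0.0218) and Gpnmb (137.9 ± 21.6 against 35.3 ± 9.58, 1.97, SE 0.21, 0.000839) were higher too, as were the histone gene H2ac19 (3.35, SE 0.63, 0.00933) and the small RNA gene Rnu3a, listed at 0 in GFP-negative libraries. Glycolysis rose with 8 of 18 genes (12 alone, camera adjusted p = 1.69e-12, adjusted p = 0.0532 with an estimated correlation). It was led by Aldoa at 1635 against 1012 TPM (0.70, SE 0.11, 0.00485) and Gapdh at 5255 against 3410 (0.63, SE 0.13, 0.0135). Disease-associated genes rose with 8 of 32 (17 up and 2 down alone, 5.53e-14), amoeboid microglia genes with 8 of 24 (13 alone, 2.14e-15), and iron with redox genes with 4 up and 1 down of 22 (4 and 2 alone, 2.06e-06). The ferritin chain Fth1 was at 13010 against 7771 TPM. Chemokines and cytokines rose with 3 of 25 (7 alone, 1.11e-06, adjusted p = 0.0849 with an estimated correlation). Il1a was at 258.2 against 97.4 and Ccl3 at 1504 against 771 TPM.

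Genes lower in glioma GFP-positive libraries were those of dendritic cells, 8 of 10 (8 alone, camera adjusted p = 2.37e-08, adjusted p = 0.0884 with an estimated correlation), such as Flt3 (log2 fold change -2.52) and Itgae (-2.16). Markers of monocyte-derived cells fell, 7 of 24 (1 up and 12 down alone, 0.00324, adjusted p = 0.43 with an estimated correlation), and so did homeostatic genes, 12 of 28 (23 alone, 2.72e-12, adjusted p = 0.16 with an estimated correlation). P2ry12 was 231.8 against 1262 TPM (-2.35, SE 0.35, 0.0034), Siglech 74.9 against 480.2 (-2.68, SE 0.38, 0.0024) and Plac8 449 against 1611 (-1.96). Further falls were Retnlg (0.190 ± 0.380 against 68.1 ± 28.4 TPM, -5.79, SE 0.33, 3.14e-06), G0s2, an inhibitor of lipolysis (0.110 ± 0.220 against 14.8 ± 3.87, -3.82, SE 0.34, 0.000185), and Ifitm6 (9.22 ± 6.83 against 105.5 ± 28.7, -3.57, SE 0.41, 0.00116). They were followed by Serpinb2 (-3.48, SE 0.47, 0.00223), Adgre4 (-3.19, SE 0.35, 0.000916), Thrsp (-3.18, SE 0.33, 0.000763), Cd209a (18.7 ± 14.2 against 134.9 ± 42.8, -3.05, SE 0.55, 0.00799) and Ear2 (-2.96, SE 0.53, 0.0076). Of 7 neutrophil genes 2 fell (2 alone, 0.0563). How far other cells among the sorted GFP-negative cells account for these falls was not tested. Called up were border-associated macrophage markers (1 of 16, 2 up and 1 down alone, 0.00127, adjusted p = 0.376 with an estimated correlation) and T cell markers (0 of 11, 0 alone, 0.00787, adjusted p = 0.43). There were 965 called genes, 134 up and 831 down (13.9% up). With rescaled values 302 were up and 450 down (40.2% up), and before it the median of all genes was -0.15. The count was 420 without GFP-negative library 2, and 619, 537 and 505 without GFP-positive libraries 2, 3 and 4.

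Between GFP-negative cells of tumour mice and controls (4 against 4 libraries) 7637 of 14461 genes were called, and the interferon response took part with all 28 of its 28 genes up (28 alone, camera adjusted p = 2.67e-36). Isg15 stood at 622.4 against 8.99 TPM (log2 fold change 5.96, SE 0.22, adjusted p = 8.84e-10) and Cxcl10 at 635.1 against 5.90 (6.66). Ly6c2, a surface marker of monocytes, reached 906 ± 661 against 0.755 ± 0.802 TPM (8.90, SE 0.52, 4.94e-08) and Ifi205 448 ± 172 against 0.255 ± 0.226 (8.42, SE 0.30, 8.84e-10). Complement factor Cfb reached 565 ± 161 against 1.06 ± 1.42 (8.32, SE 0.37, 4.9e-09) and Ccl5 1166 ± 451 against 4.39 ± 2.01 (7.80, SE 0.32, 2.38e-09). Ccr7 at 231 ± 115 and Serpina3g at 215 ± 85.7 TPM were listed at 0 in the controls. Transthyretin, Ttr, a gene of the choroid plexus, fell from 735 ± 700 to 20.9 ± 18.5 (-4.79, SE 1.10, 0.00283). Lower too were Enpp2 (-4.21, SE 0.79, 0.000772), H2ac19 (-4.13, SE 0.63, 0.000179), the receptor gene Gpr165 (-3.73, SE 0.38, 7.7e-06), Tmem204 (-3.44, SE 0.41, 2.91e-05) and Klhdc8b (-3.11, SE 0.37, 2.85e-05).

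By list, glioma GFP-negative libraries were above control for MHC class I (17 of 17, 17 alone, camera adjusted p = 2.63e-20), with H2-K1 at 6749 against 922 TPM, and for MHC class II (9 of 12, 9 alone, 1.45e-09), with Cd74 at 9738 against 632.1 TPM. Chemokines and cytokines (21 of 25, 21 alone, 1.34e-15), NF-kB targets (17 up and 1 down of 19, 17 and 1 alone, 3.03e-11) and the cell cycle (26 of 30, 27 alone, 3.47e-18, adjusted p = 0.0743 with an estimated correlation) rose. The mitotic kinase Aurkb was at 24.5 against 1.15 TPM. All 24 monocyte-derived markers rose (24 alone, 3.47e-18), with Plac8 at 1611 against 23.5 TPM. NK cell markers rose 11 of 11 (11 alone, 1.47e-08, adjusted p = 0.0991 with an estimated correlation), T cell markers 8 of 11 (8 alone, 3.67e-05, adjusted p = 0.169) and dendritic cell markers 8 of 10 (8 alone, 1.09e-05, adjusted p = 0.115). For border-associated macrophage markers it was 9 up and 1 down of 16 (10 and 1 alone, 1.6e-05, adjusted p = 0.169) and neutrophil markers 5 up and 1 down of 7 (5 and 1 alone, 0.0011). The T cell gene Lck was 8.33 against 0.193 TPM and the NK cell gene Nkg7 40.7 against 0.295. Disease-associated genes split, 16 up and 9 down of 32 (16 and 9 alone, 1.2e-06), with Apoe at 14560 against 1930 TPM. Of 28 homeostatic genes 27 fell (27 alone, 1.47e-08, adjusted p = 0.191 with an estimated correlation), Fcrls to 451.7 from 3147 TPM.

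Immediate early and heat shock genes rose in the same comparison, 17 up and 1 down of 29 (18 and 1 alone, camera adjusted p = 2.93e-08, adjusted p = 0.115 with an estimated correlation). Fos was at 501.6 ± 221 against 175.4 ± 12.1 TPM (log2 fold change 1.42, SE 0.25, adjusted p = 0.00053). In no group of the other models did Fos average above 3.47 TPM, so the glioma controls were already high. The cause was not tested. Matrix remodelling (18 of 25, 18 alone, 3.03e-11), lipid handling (17 up and 7 down of 28, 17 and 7 alone, 2.07e-06) and iron with redox genes (12 up and 3 down of 22, 12 and 3 alone, 1.45e-05) rose. Hypoxia (12 up and 4 down of 20, 12 and 4 alone, 0.00106, adjusted p = 0.0946 with an estimated correlation) and cholesterol synthesis (9 up and 2 down of 22, 9 and 1 alone, 0.00234, adjusted p = 0.38 with an estimated correlation) were called up. Phagocytic receptors with complement (8 up and 13 down of 26, 8 and 14 alone, 0.782), the lysosome (3 up and 13 down of 32, 3 and 13 alone, 0.928) and the unfolded protein response (2 up and 7 down of 22, 2 and 7 alone, 0.782) were not. In rescaled values the lysosome had 11 up and 5 down, phagocytic receptors 9 and 7 and the unfolded protein response 6 and 2. Lists of B cells (2 up and 3 down of 5, 2 and 3 alone, 0.986), oligodendrocytes (1 and 4 of 8, 1 and 4 alone, 0.799), and their precursors (3 up of 4, 3 alone, 0.0898) were not called. Neither were those of astrocytes (5 and 2 of 10, 5 and 2 alone, 0.293), neurons (1 and 1 of 6, 1 and 1 alone, 0.928), endothelial cells with pericytes (1 and 5 of 12, 1 and 5 alone, 0.942) and erythroid cells (0 of 5, 0 alone, 0.471). In all 2314 genes were up and 5323 down (30.3% up). After rescaling it was 3205 and 2321 (58.0% up), and before it the median of all genes was -0.37.

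GFP-positive cells of glioma mice differed from the controls (4 against 4 libraries) in 9205 genes, 2561 up and 6644 down (27.8% up). Rescaling changed this to 3946 and 3548 (52.7% up), and before it the median over all genes was -0.51. Cfb (876 ± 170 against 1.06 ± 1.42 TPM, log2 fold change 8.97, SE 0.37, adjusted p = 2.26e-09) and the arginase gene Arg1 (923.7 ± 689 against 1.43 ± 2.43, 8.48, SE 0.88, 3.98e-06) rose. Ly6c2 (8.34, SE 0.52, 5.86e-08), the interleukin 1 antagonist Il1rn (672.9 ± 181 against 2.998 ± 3.03, 7.77, SE 0.54, 1.41e-07) and Ccl5 (7.72, SE 0.32, 2.35e-09) rose as well, and Serpina3g was listed at 0 in the controls. Gpr165 (0.333 ± 0.291 against 83.7 ± 7.71, -6.01, SE 0.38, 6.67e-08), the fructose transporter Slc2a5 (15.8 ± 9.20 against 607.5 ± 60.7, -5.37, SE 0.38, 1.84e-07) fell. Hpgd, which breaks down prostaglandins (-5.29, SE 0.25, 6.63e-09), Thrsp (-5.25, SE 0.33, 6.25e-08), Upk1b (-5.23, SE 0.38, 2.13e-07) and Tmem204 (-5.22, SE 0.41, 4.39e-07) followed. All 28 homeostatic genes fell (28 alone, camera adjusted p = 1.25e-09, adjusted p = 0.165 with an estimated correlation).

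EAE tests the reactive state under autoimmune inflammation (GFP-positive against GFP-negative, 3 against 3 libraries). Gpnmb (146 ± 20.5 against 20.7 ± 8.80 TPM, log2 fold change 2.83, SE 0.28, adjusted p = 0.00169), Igf1 (60.7 ± 6.34 against 8.83 ± 1.20, 2.65, SE 0.29, 0.00342) and fibronectin, Fn1 (87.3 ± 7.21 against 14.3 ± 3.82, 2.56, SE 0.29, 0.00374), rose beside Spp1. Colec12 (23.3 ± 6.27 against 3.93 ± 1.77, 2.34, SE 0.34, 0.0137), Lilr4b (2.20, SE 0.42, 0.0486), Ms4a7 (2.09, SE 0.26, 0.00653) and Lpl (244 ± 18.2 against 59.1 ± 8.89, 2.04, SE 0.20, 0.00169) were higher as well. Of the disease-associated genes 9 of 32 rose (19 alone, camera adjusted p = 4.85e-20), with Clec7a at 472.9 against 210.5 TPM (1.16, SE 0.10, 0.00134) and Cst7 at 1722 against 875. Amoeboid microglia genes rose with 8 of 24 (18 alone, 1.53e-24) and lipid handling with 5 of 26 (13 alone, 6.95e-12). Markers of monocyte-derived cells fell, 1 up and 4 down of 16 (1 and 7 alone, 1.33e-05). Genes that fell in EAE were Ifitm1 (0.703 ± 0.620 against 32.6 ± 14.7, -4.26, SE 0.57, 0.00986), Plac8 (3.17 ± 3.31 against 44.3 ± 20.0, -3.66, SE 0.60, 0.0279) and Plbd1 (-3.34, SE 0.56, 0.0307). Others were the calcium-binding protein gene S100a4 (0.727 ± 0.637 against 14.8 ± 3.64, -3.25, SE 0.39, 0.00544), the protease gene Napsa (-3.19, SE 0.55, 0.0324), Cnn2 (-1.50, SE 0.29, 0.0486), Clec4a2 (-1.46, SE 0.18, 0.00544) and Hmgb2 (-1.44, SE 0.25, 0.032).

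In EAE the interferon response was lower in GFP-positive cells, with 3 of 28 down (8 alone, camera adjusted p = 1.65e-09), the genes Rtp4, Ifi27l2a and Xaf1, and 0 of the 28 were called after rescaling. Homeostatic genes fell with 10 of 28 (1 up and 15 down alone, 2.88e-15), P2ry12 to 984 from 1901 TPM (log2 fold change -0.95, SE 0.07, adjusted p = 0.00126), and MHC class II fell as a list with 0 of 12 called (3 alone, 2.53e-05). Markers of dendritic cells (1 of 7, 5 alone, 2.57e-06, adjusted p = 0.0958 with an estimated correlation) and B cells (1 of 4, 1 up and 2 down alone, 0.02, adjusted p = 0.0893 with an estimated correlation), which carry class II, fell too. Oxidative phosphorylation fell with 0 of 38 called (0 alone, 5.11e-06, adjusted p = 0.242 with an estimated correlation). The contrast called 93 of 13513 genes, 34 up and 59 down (36.6% up). With rescaled values 36 were up and 41 down (46.8% up), and before it the median of all genes was 0.05, and with the replicate block 8 were up and 5 down. Leaving out GFP-negative library 1, 2 or 3 gave 211, 50 or 41, and leaving out GFP-positive library 1, 2 or 3 gave 33, 26 or 25.

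MHC class II set EAE GFP-negative cells apart from controls (3 against 3 libraries). H2-Aa reached 2101 ± 361 against 14.1 ± 21.1 TPM (log2 fold change 8.36, SE 0.88, adjusted p = 0.000116) and H2-Eb1 1726 ± 169 against 16.2 ± 23.4 (7.68, SE 0.75, 7.13e-05), with 9 up and 1 down of 12 in the list (9 and 1 alone, camera adjusted p = 1.07e-13). Cfb (209.6 ± 13.8 against 0.613 ± 1.06, 7.21, SE 0.34, 4.05e-07), Ccl5 (807 ± 198 against 5.11 ± 4.03, 7.21, SE 0.36, 5.12e-07) and H2-Q7 (865 ± 125 against 6.23 ± 5.42, 7.19, SE 0.43, 1.93e-06) rose. The interferon-induced GTPase gene Iigp1 was at 146 ± 40.0 TPM with the controls listed at 0. The interferon response rose with 26 of 28 (27 alone, 3.95e-50), and MHC class I with 15 of 17 (16 alone, 6.43e-29). Disease-associated genes rose with 21 up and 4 down of 32 (22 and 5 alone, 1.08e-23) and monocyte-derived markers with 8 up and 1 down of 16 (8 and 1 alone, 1.47e-08). Cst7 was 875 against 25.3 TPM and Apoe 39810 against 4141. Gpr165 (1.13 ± 1.03 against 48.9 ± 11.9, -4.66, SE 0.42, 4.2e-05), Gp9 (-3.38, SE 0.37, 0.000154) and Klhdc8b (-3.35, SE 0.37, 0.00016) fell. Sema4b (-3.27, SE 0.33, 9.27e-05), the flagellin receptor Tlr5 (-3.24, SE 0.28, 3.08e-05) and Rac3 (-3.22, SE 0.33, 9.53e-05) fell too. Homeostatic genes fell in 24 of 28 cases (27 alone, 1.1e-13), 16 after rescaling.

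For lipid handling in this EAE comparison the median was -0.01, the mean 0.85 and the test up (10 up and 4 down of 26, 10 and 4 alone, camera adjusted p = 1e-07). For phagocytic receptors the median was -0.12, the mean 0.21 and the test up (6 up and 7 down of 26, 7 and 10 alone, 0.0213, adjusted p = 0.155 with an estimated correlation). The total was 4099 genes, 794 up and 3305 down (19.4% up). After rescaling it was 1222 and 625 (66.2% up), and before it the median of all genes was -0.47. It was 2332, 2168 and 2633 without controls 1, 2 and 3. GFP-positive EAE cells against controls (3 against 3) gave 4025 genes, 934 up and 3091 down (23.2% up). Rescaling changed this to 1421 and 921 (60.7% up), and before it the median over all genes was -0.41. H2-Aa at 1805 ± 39.7 TPM (log2 fold change 8.15, SE 0.88, adjusted p = 9.63e-05), Cfb (7.46, SE 0.34, 2.28e-07), Ccl5 (7.26, SE 0.36, 3.72e-07) and H2-Eb1 (7.20, SE 0.75, 7.75e-05) rose. Saa3 at 222.8 ± 53.5 and Iigp1 at 147 ± 19.1 TPM were listed at 0 in the controls. Gpr165 (-5.22, SE 0.42, 1.14e-05), Gp9 (-4.64, SE 0.37, 1.03e-05) and Tmem204 (-4.31, SE 0.25, 1.29e-06) fell. Hpgd (42.6 ± 7.65 against 693.2 ± 69.8, -4.00, SE 0.19, 3.31e-07) and Cask (-3.65, SE 0.30, 1.26e-05) were lower too, and Tlr5 was listed at 0.

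5xFAD mice carry amyloid, and their GFP-positive and GFP-negative microglia (4 against 4 libraries) differed in disease-associated genes, 23 of 32 up (28 alone, camera adjusted p = 3.67e-45). Gpnmb (172 ± 62.0 against 17.1 ± 10.2 TPM, log2 fold change 3.38, SE 0.40, adjusted p = 9.3e-05), the proton pump subunit Atp6v0d2 (12.2 ± 4.45 against 0.335 ± 0.5684, 3.31, SE 0.41, 0.000134) and Apoc1 (12.97 ± 6.88 against 0.565 ± 1.13, 3.22, SE 0.70, 0.0094) rose beside Spp1. Mmp12 (2.61, SE 0.76, 0.0465), the folate receptor Folr1 (2.61, SE 0.45, 0.00213), Cck, the gene for cholecystokinin (43.4 ± 13.03 against 7.23 ± 3.84, 2.57, SE 0.69, 0.0324), and Ctnna3 (2.52, SE 0.42, 0.00164) followed. Apoe was 91280 against 33570 TPM (1.45, SE 0.11, 2.19e-06) and Igf1 321.6 against 86.8 (1.90, SE 0.26, 0.000304). Lysosomal genes rose with 13 up and 2 down of 31 (16 and 2 alone, 2.31e-15), amoeboid microglia genes with 13 of 24 (18 alone, 7.91e-31) and growth factors with 3 of 13 (4 alone, 3.74e-06). Also called up was MHC class II with 4 of 12 (4 up and 3 down alone, 0.00364, adjusted p = 0.239 with an estimated correlation), and H2-Aa was at 336.7 against 76.3 TPM (2.05, SE 0.36, 0.0021).

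The genes falling most in 5xFAD GFP-positive cells were the transporter Slco4a1 (0.693 ± 0.868 against 16.8 ± 5.09 TPM, log2 fold change -3.49, SE 0.43, adjusted p = 0.000117), the transglutaminase Tgm2 (0.763 ± 1.08 against 14.0 ± 6.54, -3.18, SE 0.40, 0.000144) and Tmem204 (-3.15, SE 0.48, 0.000799). They were followed by Tmem170b (8.22 ± 3.15 against 67.2 ± 19.7, -2.89, SE 0.36, 0.00015), Cass4 (-2.73, SE 0.48, 0.00226), Ggta1 (-2.72, SE 0.28, 2.95e-05), the adhesion gene Pecam1 (-2.61, SE 0.36, 0.000341) and Grap (-2.54, SE 0.26, 2.95e-05). Homeostatic genes fell, 19 of 28 (21 alone, camera adjusted p = 2.34e-20), with P2ry12 at 2316 against 5354 TPM (-1.20, SE 0.07, 3.11e-07) and Tmem119 at 920.6 against 2684 (-1.56). In the whole comparison 1023 of 12532 genes were called, 128 up and 895 down (12.5% up). With rescaled values 406 were up and 248 down (62.1% up), and before it the median of all genes was -0.29. It was 647 without GFP-negative library 3 and 637 without GFP-negative library 4.

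In 5xFAD, GFP-negative microglia already differed from wild type (4 against 4 libraries). Cst7, an inhibitor of cathepsins, stood at 2522 ± 289 against 31.4 ± 15.96 TPM (log2 fold change 6.48, SE 0.32, adjusted p = 4.88e-09) and Ch25h at 138.7 ± 29.3 against 1.61 ± 1.46 (5.92, SE 0.35, 4.34e-08). Igf1 was at 86.8 ± 19.5 against 1.07 ± 0.890 (5.47, SE 0.26, 3.69e-09), Actr3b at 29.3 ± 4.63 against 0.0875 ± 0.175 (4.80, SE 0.26, 1.78e-08) and Baiap2l2 at 34.4 ± 4.64 TPM with the controls listed at 0. The pseudogene Rpl34-ps1 was at 529.8 ± 93.2 against 0.448 ± 0.895 (8.66, SE 0.34, 3.06e-10). Disease-associated genes rose with 29 of 32 (29 alone, camera adjusted p = 7.43e-71), Apoe to 33570 from 2860 TPM (3.55, SE 0.11, 2.26e-11). The interferon response rose with 19 of 28 (23 alone, 5.14e-29) and lysosomal genes with 17 up and 2 down of 31 (18 and 2 alone, 1.3e-22), Ctsd at 41290 against 19070 TPM. Cholesterol synthesis rose with 6 of 22 (6 alone, 6.28e-07) and the hypoxia response with 4 of 14 (4 alone, 2.93e-05). For growth factors the median was -0.14, the mean 0.63 and the test up (4 of 13, 4 alone, 0.00126).

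Lower in 5xFAD GFP-negative cells than in wild type were Fcrl1 (1.61 ± 2.38 against 61.0 ± 15.2 TPM, log2 fold change -4.96, SE 0.65, adjusted p = 0.000159), Plbd1 (-2.995, SE 0.69, 0.00992) and Mgl2 (-2.94, SE 0.62, 0.00601). Lower as well were lymphotoxin beta, Ltb (-2.70, SE 0.39, 0.000379), Tslp (-2.53, SE 0.57, 0.0088) and Ms4a4a, listed at 0 against 10.9 ± 9.70 TPM. Dendritic cell markers fell with 2 of 4 (4 alone, camera adjusted p = 0.0155), and homeostatic genes with 25 of 28 (27 alone, 3.4e-15), 8 of them after rescaling. For MHC class II 1 gene rose and 4 fell of 12 (1 and 6 alone, 0.0743), with H2-Aa at 76.3 against 288.3 TPM (-1.83). The comparison called 1591 genes, 448 up and 1143 down (28.2% up). After rescaling it was 686 and 213 (76.3% up), and before it the median of all genes was -0.28, and 999, 1058 and 1029 without GFP-negative libraries 1, 2 and 3. GFP-positive 5xFAD cells against wild type (4 against 4) gave 5017 genes, 766 up and 4251 down (15.3% up). Rescaling changed this to 1520 and 1079 (58.5% up), and before it the median over all genes was -0.57. Cst7 at 6893 ± 553 (7.93, SE 0.32, 1.37e-10), Igf1 at 321.6 ± 29.6 (7.37, SE 0.26, 6.31e-11) rose, as did Ch25h (7.31, SE 0.35, 8.92e-10), Gpnmb at 172 against 0.270 (7.08, SE 0.40, 5e-09) and Rpl34-ps1 (8.73, SE 0.34, 1.09e-10). Tgm2 (-5.05, SE 0.40, 1.4e-07), Tmem204 (-4.97, SE 0.48, 1.39e-06), and Slco4a1 (-4.85, SE 0.43, 4.68e-07) fell. Cd209a (-4.75, SE 0.78, 0.000222), Bank1 (-4.57, SE 0.44, 1.38e-06) and Ggta1 (-4.31, SE 0.28, 2.1e-08) fell as well.

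After the stroke at P6, when microglia are still maturing, GFP-positive cells (4 against 4 GFP-negative libraries) were higher for lysosomal and disease-associated genes. Lamp1, a protein of the lysosomal membrane, was at 1450.2 ± 453 against 236.5 ± 56.3 TPM (log2 fold change 2.58, SE 0.29, adjusted p = 0.00328) and the GTPase Rac1 at 517.9 ± 305 against 52.4 ± 6.90 (3.07, SE 0.37, 0.00328). Ccl8 was at 10.5 ± 10.1 against 0.283 ± 0.565 (2.73, SE 0.57, 0.0289). Rnf187 (2.46, SE 0.49, 0.023), the sorting nexin Snx20 (37.3 ± 5.27 against 6.61 ± 2.47, 2.37, SE 0.23, 0.00127), the heparanase Hpse (2.23, SE 0.35, 0.0131) and Colec12 (2.14, SE 0.40, 0.0191) rose too. Apoe was 41540 against 23290 TPM (0.83, SE 0.10, 0.00328), Igf1 193.2 against 74.2 (1.37, SE 0.17, 0.00328) and Gpnmb 109.1 against 26.2 (2.00, SE 0.28, 0.00604). Disease-associated genes rose with 13 of 31 (19 alone, camera adjusted p = 1.06e-20) and amoeboid microglia genes with 13 of 24 (17 up and 1 down alone, 6.01e-21). Lysosomal genes rose with 4 of 30 (16 alone, 4e-14) and iron with redox genes with 4 of 21 (6 alone, 4.05e-06). Border-associated macrophage markers rose with 3 of 13 (3 alone, 0.00125, adjusted p = 0.24 with an estimated correlation). The interferon response had 0 of 28 called (0 alone, camera adjusted p = 0.871).

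Lower in P6 GFP-positive libraries were Retnlg (5.47 ± 9.67 against 126.7 ± 146 TPM, log2 fold change -4.90, SE 0.85, adjusted p = 0.0163), H2-Aa (4.94 ± 6.10 against 108.6 ± 72.7, -4.71, SE 0.81, 0.0163) and H2-Eb1 (-3.78, SE 0.77, 0.0264). Further genes to fall were Pglyrp1, which binds peptidoglycan (-3.08, SE 0.51, 0.0152), Cd24a (-2.56, SE 0.44, 0.0163) and neuroplastin, Nptn (37.99 ± 27.4 against 155 ± 19.1, -2.22, SE 0.32, 0.00769), with the Notch inhibitor Numb (-2.07, SE 0.34, 0.0152) and Map3k1 (-2.03, SE 0.50, 0.047). MHC class II fell with 4 of 10 (5 alone, camera adjusted p = 0.000765, adjusted p = 0.258 with an estimated correlation). Homeostatic genes fell with 5 of 28 (1 up and 13 down alone, 0.000355, adjusted p = 0.285 with an estimated correlation), 1 of them after rescaling, and neutrophil markers with 1 of 5 (2 alone, 0.0358, adjusted p = 0.285 with an estimated correlation). Here 441 of 13136 genes were called, 135 up and 306 down (30.6% up). With rescaled values 210 were up and 152 down (58.0% up), and before it the median of all genes was -0.12, and with the replicate block 73 were up and 59 down. Every library moved that count, to 92, 145, 173 and 196 without GFP-negative libraries 1 to 4, and to 1292, 153, 22 and 124 without GFP-positive libraries 1 to 4.

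Between GFP-negative cells of the P6 stroke and the contralateral side (4 against 4 libraries) genes of cell division were lower. The cell cycle list fell with 8 of 30 (26 alone, camera adjusted p = 3.05e-38). Genes of mitosis that fell were the spindle gene Tpx2 (13.6 ± 2.07 against 29.7 ± 4.24 TPM, log2 fold change -1.07, SE 0.16, adjusted p = 0.0167), Knstrn (-1.01, SE 0.18, 0.0389), Racgap1 (-0.99, SE 0.17, 0.0357), and Nusap1 (-0.98, SE 0.16, 0.0254). The ribonucleotide reductase gene Rrm2 (44.1 ± 4.64 against 84.4 ± 4.41, -0.92, SE 0.11, 0.00923) fell too, and Llph-ps2 fell by -2.89 (SE 0.52, 0.0392). H2-Aa (108.6 ± 72.7 against 0.0425 ± 0.0850, 6.35, SE 0.81, 0.0103), H2-Eb1 (91.6 ± 61.6 against 0.503 ± 0.441, 5.65, SE 0.77, 0.0119), Cd24a (3.41, SE 0.44, 0.0103) and Pglyrp1 (3.38, SE 0.51, 0.0185) rose. Retnlg (126.7 ± 146 TPM, adjusted p = 0.0115) and the lipoxygenase Alox15 (14.2 ± 14.9 TPM, 0.0434) were listed at 0 on the contralateral side. MHC class II rose with 3 of 10 (6 alone, 2.38e-12), neutrophil markers with 1 of 5 (2 alone, 1.6e-06) and monocyte-derived markers with 1 of 16 (3 alone, 1.6e-06, adjusted p = 0.0637 with an estimated correlation). Disease-associated genes rose with 1 of 31 (3 alone, 3.46e-05, adjusted p = 0.16 with an estimated correlation), Apoe at 23290 against 14530 TPM (0.69, SE 0.10, 0.0185). The 36 called genes, 12 up and 24 down (33.3% up), were 9 and 10 (47.4% up) after rescaling and 5 and 6 with the replicate block. The median was -0.05, and 1051 genes were at an unadjusted limma p under 0.05. Without contralateral libraries 1 to 4 the count was 3, 8, 16 and 5, and without GFP-negative libraries 1, 2 and 4 it was 23, 5 and 6.

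Against the contralateral side, P6 GFP-positive cells (4 against 4 libraries) had higher Rac1 (log2 fold change 2.91, SE 0.37, adjusted p = 0.00183), Gpnmb (109.1 ± 30.8 against 14.5 ± 5.91 TPM, 2.86, SE 0.28, 0.000513), Colec12 (2.48, SE 0.40, 0.00819) and Hpse (2.22, SE 0.35, 0.00772), and Ccl8 was listed at 0 on the contralateral side. Nptn (-1.68, SE 0.32, 0.0213), Arhgap21 (-1.68, SE 0.42, 0.0484), Pdcd4 (-1.49, SE 0.33, 0.0353), Tstd1 (-1.37, SE 0.33, 0.0413) and Pank4 (-1.35, SE 0.28, 0.028) fell. The cell cycle was lower in these cells too, with 9 of 30 (23 alone, camera adjusted p = 5.78e-11), and disease-associated genes higher with 13 of 31 (21 alone, 2.63e-35). Border-associated macrophage markers (3 of 13, 3 alone, 1.66e-05, adjusted p = 0.0809 with an estimated correlation) and monocyte-derived markers (1 of 16, 1 alone, 0.00173, adjusted p = 0.145) rose too. Homeostatic genes fell with 7 of 28 (16 alone, 2.31e-05, adjusted p = 0.195 with an estimated correlation), 0 of them after rescaling. The total of 409 genes, 73 up and 336 down (17.8% up), was 107 and 41 (72.3% up) after rescaling and 31 and 16 with the replicate block, and the median in TPM was -0.17. It moved to 53, 71, 153 and 63 without contralateral libraries 1 to 4 and to 1195, 215, 69 and 68 without GFP-positive libraries 1 to 4.

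The P28 stroke gave the largest contrast by the gate (4 against 4 libraries). Igf1 (93.0 ± 54.8 against 3.91 ± 3.09 TPM, log2 fold change 4.28, SE 0.51, adjusted p = 8.77e-05), Fn1 (77.4 ± 60.9 against 2.39 ± 1.10, 4.11, SE 0.55, 0.000181) and the fatty acid binding protein Fabp3 (27.7 ± 7.52 against 1.37 ± 2.15, 3.95, SE 0.50, 0.000123) rose beside Spp1. Apoc1 (3.83, SE 0.68, 0.00109), Mmp12 (20.7 ± 6.67 against 0.593 ± 0.785, 3.82, SE 0.33, 1.33e-05), Ch25h (247 ± 122 against 19.4 ± 12.3, 3.77, SE 0.52, 0.000205) and serum amyloid Saa3 (3.77, SE 0.65, 0.000902) followed, and Apoe stood at 25930 against 3056 TPM (3.14, SE 0.24, 6.89e-06). Disease-associated genes rose with 28 of 32 (30 alone, camera adjusted p = 8.74e-47), with Cd52 at 1405 against 337.6 TPM (2.04, SE 0.19, 2.16e-05). The interferon response rose with 27 of 28 (27 alone, 7.97e-37), with Ifitm3 at 745.4 against 115.5 (2.67, SE 0.30, 6.89e-05) and Isg15 at 59.5 against 10.1 (2.35). MHC class I rose with 12 of 17 (12 alone, 8.19e-17), with B2m at 11410 against 5526 TPM (1.05). The cell cycle rose with 13 up and 1 down of 29 (14 and 1 alone, 9.76e-13), with Mki67 at 3.64 against 0.343 (1.78, SE 0.30, 0.00077).

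Further lists higher in P28 GFP-positive cells were matrix remodelling (13 of 20, 16 alone, camera adjusted p = 8.45e-18), amoeboid microglia (23 of 24, 24 alone, 9.52e-40), oxidative phosphorylation (14 up and 1 down of 38, 14 and 2 alone, 1e-08) and monocyte-derived cells (5 of 15, 5 alone, 1.02e-06). Homeostatic genes fell with 24 of 28 (26 alone, 1.42e-13), and after rescaling 2 rose and 17 fell, with Tmem119 at 1454 against 3408 TPM (log2 fold change -1.24, SE 0.11, adjusted p = 1.34e-05). Gpr165 (24.8 ± 15.7 against 123 ± 28.9, -2.42, SE 0.31, 0.000122), Sema4b (-2.28, SE 0.31, 0.000174) and Tlr5 (5.54 ± 4.56 against 26.3 ± 1.09, -2.27, SE 0.31, 0.000186) fell. Ccdc162 (-2.23, SE 0.32, 0.000287), Upk1b (-2.20, SE 0.24, 4.91e-05), Bank1 (-2.09, SE 0.21, 3.48e-05), Tmem204 (-2.03, SE 0.19, 2.31e-05) and Gp9 (-1.91, SE 0.22, 7.51e-05) followed. Of 14303 genes 4154 were called, 838 up and 3316 down (20.2% up). After rescaling it was 1418 and 822 (63.3% up), and before it the median of all genes was -0.30.

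GFP-negative cells of the P28 stroke were close to the contralateral side (4 against 4 libraries), with 34 called genes. With the replicate block in the fit 0 of them were called. Ifi27l2a was at 155.5 ± 69.5 against 23.6 ± 8.74 TPM (log2 fold change 2.57, SE 0.44, adjusted p = 0.033) and the class I gene H2-Q7 at 29.8 ± 11.01 against 3.71 ± 1.25 (2.68, SE 0.29, 0.00411). Cxcl10 was at 16.8 ± 9.98 against 1.49 ± 1.84 (3.03, SE 0.57, 0.0496) and Ch25h at 19.4 ± 12.3 against 0.993 ± 0.673 (3.14, SE 0.52, 0.031). Vimentin, Vim (2.69, SE 0.48, 0.0402), and the complement gene C4b (2.28, SE 0.35, 0.0213) rose too. The long noncoding RNA Malat1 fell from 7327 ± 1148 to 4718 ± 683 (-0.63, SE 0.12, 0.0466). The interferon response rose with 6 of 28 (22 alone, camera adjusted p = 5.03e-29), MHC class I with 4 of 17 (9 alone, 5.13e-17) and disease-associated genes with 5 of 32 (17 alone, 1.45e-25). MHC class II (0 of 12, 0 alone, 8.63e-05, adjusted p = 0.159 with an estimated correlation) and monocyte-derived markers (0 of 15, 0 alone, 0.0194, adjusted p = 0.374) were called up as lists. Of the 34 genes 31 were up and 3 down. The median was -0.01, and 1216 genes were at an unadjusted limma p under 0.05. Without contralateral libraries 1 to 4 the count was 7, 5, 15 and 14, and without GFP-negative libraries 1, 2 and 3 it was 2, 2 and 15.

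P28 GFP-positive cells differed from the contralateral side (4 against 4 libraries) in 5150 genes, 1082 up and 4068 down (21.0% up). Rescaling changed this to 1819 and 1257 (59.1% up), and before it the median over all genes was -0.33. Ifi27l2a rose to 1649.8 ± 764 TPM (log2 fold change 5.98, SE 0.44, adjusted p = 6.3e-07) and Ch25h by 6.91 (SE 0.52, 7.61e-07). Cst7 rose to 1304 ± 370 from 27.2 ± 10.7 (5.56, SE 0.34, 2.39e-07), Cxcl10 by 5.54 (SE 0.57, 1.08e-05) and Ccl5 by 5.49 (SE 0.82, 0.000217). Gpr165 (-3.07, SE 0.31, 9.11e-06), Ccdc162 (-3.01, SE 0.32, 1.45e-05), Sema4b (-2.78, SE 0.31, 1.8e-05), Tlr5 (-2.77, SE 0.31, 1.96e-05), Upk1b (-2.47, SE 0.24, 6.42e-06) and Bank1 (-2.42, SE 0.21, 3.16e-06) fell. The interferon response rose with 27 of 28 (27 alone, camera adjusted p = 3.68e-41), the cell cycle with 19 of 29 (20 up and 1 down alone, 2.44e-13) and monocyte-derived markers with 8 of 15 (9 alone, 2.06e-07).

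**Figure D2:**
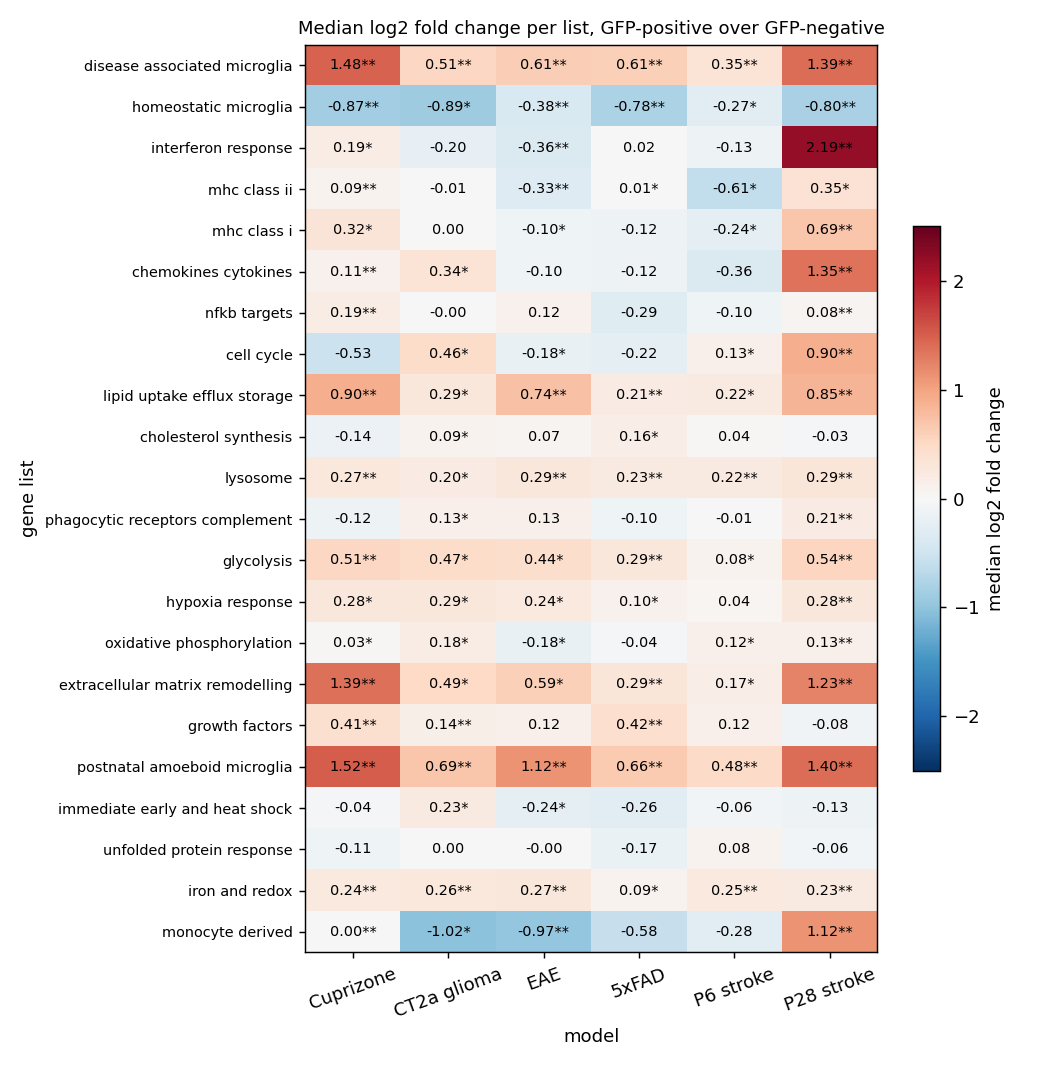
Median log2 fold change of each gene list in GFP-positive over GFP-negative libraries of the 6 models. Stars mark lists with a camera adjusted p under 0.05, 2 stars those also called with an estimated correlation.

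The genes shared by all 6 models number 11 of the 11301 tested in every table, 6 higher and 5 lower in GFP-positive cells. In the order cuprizone, glioma, EAE, 5xFAD, P6 and P28, the log2 fold changes were 4.07, 1.97, 2.83, 3.38, 2.00 and 3.68 for Gpnmb, and 4.65, 2.39, 2.65, 1.90, 1.37 and 4.28 for Igf1. They were 2.71, 2.09, 2.34, 2.29, 2.14 and 1.71 for Colec12, and 4.08, 1.00, 0.93, 1.45, 0.83 and 3.14 for Apoe. The lysosomal gene Pld3 rose by 1.29, 0.81, 1.13, 0.88, 0.415 and 1.04. Sting1, which senses cytosolic cyclic dinucleotides, changed by -0.90, -0.55, -0.75, -0.98, -0.49 and -0.74, and the checkpoint gene Vsir by -0.85, -0.97, -0.50, -0.83, -0.455 and -0.95. Rogdi changed by -0.66, -1.34, -0.54, -0.96, -0.53 and -0.81, the leukotriene synthase Ltc4s by -1.29, -2.01, -0.80, -0.89, -0.38 and -0.835, and the lectin Siglech by -0.99, -2.68, -0.94, -0.36, -0.41 and -0.95. With Spp1 these are all 11, and independent tables would share 4.06e-08 up and 0.000162 down.

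The shared genes are spread over 7 chromosomes of GRCm38. Spp1 is on chromosome 5 (104435118 to 104441050), Gpnmb on 6 (49036546 to 49070929), and Igf1 on 10 (87858265 to 87937042). Colec12 is on 18 (9707595 to 9882644), Apoe on 7 (19696109 to 19699188), Pld3 on 7 (27532000 to 27553218), and Sting1 on 18 (35733679 to 35740554). Vsir is on 10 (60346851 to 60372684), Rogdi on 16 (5008730 to 5013553), Ltc4s on 11 (50236461 to 50238616) and Siglech on 7 (55768178 to 55778925). Counting these too, 17 genes rose and 39 fell in 5 tables or more. Fabp5, Lpl, Clec7a, Capg, Anxa5, Mif, Pkm, Ftl1, Fth1, Pgk1 and Ctsd are among the former and P2ry12, Slc2a5, Adgrg1, Selplg, Sall1, Gpr34, Cst3, Il10ra and Ifngr1 among the latter. In 4 models or more 38 genes rose and 200 fell. Calls in both directions were found for 70 genes. After rescaling 7 genes rose in all 6 models, Clec7a, Colec12, Gpnmb, Igf1, Pkm, Pld3 and Spp1, and 0 fell.

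**Figure D3:**
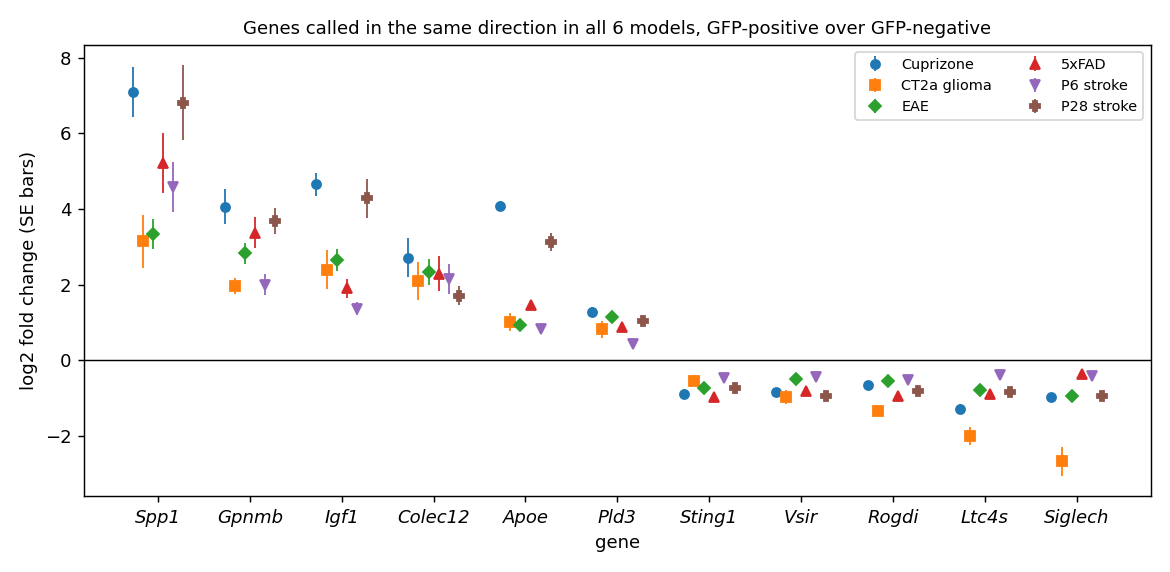
Log2 fold changes of the 11 shared genes in GFP-positive over GFP-negative libraries of the 6 models, with SE. Gpnmb ranged from 1.97 in glioma to 4.07 after cuprizone.

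At the level of single libraries, the mean of the disease-associated list was above every GFP-negative library in every GFP-positive library of the 6 models, with an exact permutation p = 0.0286 in the 4 tables of 4 against 4 and an exact permutation p = 0.1 in the 2 tables of 3 against 3, the smallest these sizes allow. Its difference was 1.78 after cuprizone, 0.59 in glioma, 0.76 in EAE, 0.88 in 5xFAD, 0.50 in the P6 and 1.79 in the P28 stroke.

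How far the models differ in what the gate separates was tested gene by gene with 1 F test over the 6 contrasts. It called 2009 of 11301 genes (3690 at an unadjusted p under 0.05), and a Welch test with the spread of each table called 1900, 1492 of them in both and all 10 named genes included. Apoe had the largest F, 41.98 (limma adjusted p = 1.28e-13), and its log2 fold change spans 0.83 in the P6 stroke to 4.08 after cuprizone. Cd52 (F 30.34, 5.57e-11) changed by 1.55 after cuprizone, 0.33 in glioma, -0.03 in EAE, 0.74 in 5xFAD, 0.10 in the P6 and 2.04 in the P28 stroke. Gas7 (F 26.47) changed by 3.24, 0.29, 1.40, 1.64, -0.66 and 1.23, and Crip1 (F 24.23) by 3.94, -1.62, -1.35, 1.67, -0.51 and 2.03. The class I genes B2m (F 22.29), H2-K1 (20.73) and H2-D1 (20.65) rose in the P28 stroke by 1.05, 1.505 and 1.58, and Ggta1 (22.03) fell by -2.72 in 5xFAD. Rpl19 (21.7) and Calm2 (21.6) complete the 10.

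Amoeboid microglia genes varied between models in 21 of 24 (87.5%), the interferon response in 24 of 28 (85.7%), disease-associated genes in 26 of 31 (83.9%), matrix remodelling in 13 of 16 (81.2%) and homeostatic genes in 20 of 28 (71.4%), against 17.8% of all genes. Cholesterol synthesis had 1 of 22 (4.55%) and the unfolded protein response 0 of 18. Across genes the fold changes of cuprizone and the P28 stroke had the highest Pearson correlation, 0.510, with 242 genes up in both (19.0 if independent) and 640 down in both (255). It was followed by 5xFAD with P28 (0.425) and glioma with P28 (0.402), while EAE and the P6 stroke had the lowest, -0.00381. Genes are not independent replicates, so no p is given for these correlations.

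The 2 strokes differ in age at injury and in the time to collection, 3 and 7 days, which cannot be told apart, and the gate separated more at P28 than at P6. The difference of the 2 contrasts was called for 1242 of 12413 genes (2930 at an unadjusted limma p under 0.05). The gate effect, not the level, was higher at P6 for 746 and at P28 for 496, and after rescaling for 187 and 721. The interferon response was lower at P6 for 26 of 28 genes (27 alone, camera adjusted p = 5.84e-30, or 0.0204 with an estimated correlation). MHC class I was lower for 12 of 17 (13 alone, 4.14e-21 or 0.000478), disease-associated genes for 22 of 31 (25 alone, 9.22e-30 or 0.001) and amoeboid microglia genes for 18 of 24 (20 alone). Homeostatic genes had a higher gate effect at P6 in 13 of 28 (18 up and 1 down alone, 1.17e-08 or 0.0514). Cd52 changed by 0.10 at P6 and 2.04 at P28 (difference -1.93, limma adjusted p = 1.82e-05), B2m by -0.15 and 1.05 (-1.19, 1.67e-05), and the ribosomal gene Rpsa by -0.43 and 0.84 (-1.27, 2.31e-07). The fractalkine receptor Cx3cr1 changed by -0.05 and -0.82 (0.76, 7.71e-05), the tubulin gene Tuba1a by 0.12 and -1.36 (1.48, 3.37e-05). For oxidative phosphorylation the median was 0.02, the mean -0.08 and the test down (1 up and 4 down of 38, 1 and 4 alone, 0.0115, adjusted p = 0.274 with an estimated correlation).

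**Figure D4:**
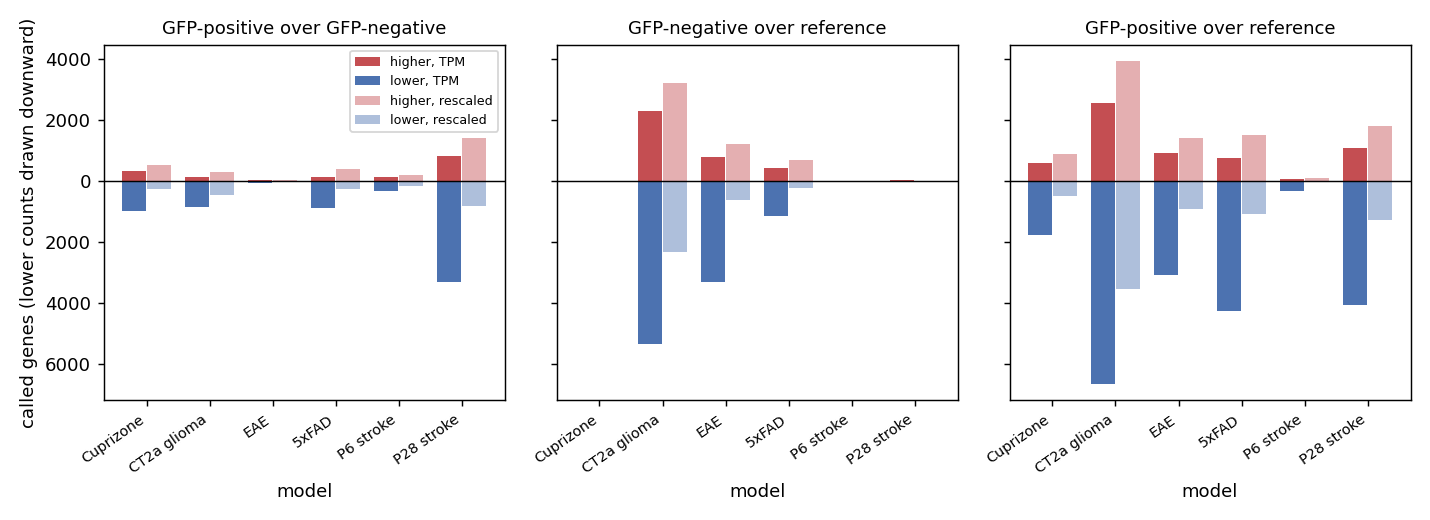
Numbers of genes called higher and lower in GFP-positive than in GFP-negative libraries, as TPM and after median-of-ratios rescaling, with lower calls drawn downward. For the P28 stroke the counts are 838 and 3316 as TPM and 1418 and 822 after rescaling.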

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

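For the groupings themselves all tests were chosen before the result was seen. With the libraries of 2 groups split in every other way and the remaining group kept in the fit, only the real split, 1 of 35, gave as many called genes in the tables with 4 libraries per group and in the contrasts with cuprizone controls. The real count and the highest other were 21 and 4 for GFP-negative and 2338 and 26 for GFP-positive cells against cuprizone controls, 965 and 240 for the gate in glioma with 7637 and 2, and 9205 and 2 against its controls, and 1023 and 2, 1591 and 7, and 5017 and 1 for the same contrasts of 5xFAD. They were 441 and 2, 36 and 8, and 409 and 2 in the P6 stroke, and 4154 and 4, 34 and 5, and 5150 and 3 in the P28 stroke. For 3 against 3 libraries there are 10 splits, which cannot reach 0.05, and the counts were 1313 and 1 for the gate after cuprizone and 93 and 5, 4099 and 3, and 4025 and 1 in EAE. Gate labels redrawn inside tables shared 0 genes, but with at most 1 cuprizone call this cannot test the 11. Redraws of GFP libraries between tables, with the table means removed and the reference groups left out, gave 1557 against 4 for the difference between 6 models and 821 against 13 for that between the 2 strokes, where the full fits gave 2009 and 1242.

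Differences between models were a planned test, and which genes and lists are given was fixed by the naming rule before the result was seen. Among the 10 genes with the largest F, Apoe had 41.98, Cd52 30.34, Gas7 26.47, Crip1 24.23, B2m 22.29, Ggta1 22.03, Rpl19 21.7, Calm2 21.6, H2-K1 20.73 and H2-D1 20.65. Between the strokes at P6 and P28 the difference was 1.48 for Tuba1a, 0.89 for Cryl1, 0.91 for Calm2, 0.76 for Cx3cr1, 0.84 for Tpst2, 1.23 for Ubl3, -1.27 for Rpsa, -0.93 for Rpl19, -1.19 for B2m, -1.93 for Cd52 and -0.85 for Eef1a1. Lists with a lower gate effect at P6 had medians of -0.93 for disease-associated microglia, -2.19 for interferon, -1.19 for MHC class I, -1.63 for chemokines, -0.17 for NF-kB targets, -0.69 for the cell cycle, -0.50 for lipid handling, -0.23 for phagocytic receptors, -0.50 for glycolysis, -1.37 for matrix remodelling, -1.22 for amoeboid microglia, -0.21 for iron with redox genes and -1.33 for monocyte-derived cells.

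Single libraries were looked for with a Dixon test chosen before the result was seen, on 8 measures in each group of 4 libraries, not in groups of 3. About 1 in 20 of these 104 tests is picked by chance, and it picked 4. Spp1 was 36.44 TPM in 5xFAD control library 3 (0 to 3.08 in the others) and 91.62 TPM in GFP-negative library 2 of the P6 stroke (5.97 to 15.05). Apoe held 2.2525% of TPM in glioma GFP-negative library 4 (1.14 to 1.2349), and the disease-associated list averaged 9.9676 in 5xFAD GFP-positive library 4 (10.001 to 10.007).

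Lower calls outnumber higher calls by the gate in all 6 models, and the median of all genes is below 0 in all but EAE. Counts over 5 tables were chosen before, and tests per table only after, the result was seen. If a few abundant genes such as Apoe took more of the fixed TPM sum, the median without genes of at least 1% would move to 0. It stayed below -0.1 in 4 of 5 tables, at -0.156 after cuprizone (-0.184 to -0.105 with 1 library left out), -0.138 in glioma (-0.152 to -0.105), -0.212 in 5xFAD (-0.234 to -0.194) and -0.301 in the P28 stroke (-0.334 to -0.286). This argues against such genes alone, but the share of ribosomal protein genes rose in all 4. The P6 stroke is open at -0.0922 (-0.121 to -0.0494). With fewer transcripts captured from GFP-positive cells, genes of at least 50 TPM would have a median near 0. It was below -0.1 in 3 of 5 tables, at -0.278 after cuprizone (-0.291 to -0.255), -0.265 in 5xFAD and -0.259 in the P28 stroke. A larger share of other genes lowers it too, so capture is undecided. Glioma at -0.0659 (-0.0723 to -0.0501) is open, the P6 stroke at -0.0221 (-0.0279 to -0.0180) has the value lower capture asks for, and no biological cause could be tested on a relative scale.

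In the P6 stroke, Retnlg, H2-Aa, H2-Eb1, Alox15, Cd24a and Pglyrp1 were higher in GFP-negative cells than on the contralateral side, and the tests for neutrophils and for MHC class II cells were chosen only after the result was seen, that for eosinophils before. Neutrophils hold far more S100a8 and S100a9 than Retnlg, but the 2 summed to a mean of 19.26 TPM, under 0.5 of Retnlg in 4 of 4 libraries (31.18 against 344.69, 12.5 against 31.55, 33.35 against 72.49 and 0 against 57.87), with Ngp at 0.745 and Camp, Ltf and Ly6g at 0, so neutrophils alone do not account for the group. Eosinophils are open, since of 10 genes of that cell 1 reached 5 TPM, Siglecf at 50.63, and it was 50.3 on the contralateral side, while Prg2 at 3.425, Ear1 at 2.662, Ear2 at 4.462, Ccr3 at 3.525, Ear6 at 0.775, Cebpe at 1.535, Il5ra at 0.1825, Epx at 0.025 and Prg3 at 0 TPM were low. For MHC class II cells Cd74 would rise, and its log2 fold change of 1.17 (SE 0.23, limma adjusted p = 0.0595) leaves that open.

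Rpl34-ps1, a processed pseudogene on chromosome 6 (71124610 to 71124963), averaged 529.8 ± 93.2 TPM in GFP-negative and 587.3 ± 242 TPM in GFP-positive 5xFAD libraries and at most 15.12 TPM in 55 libraries of other models, and every test of it was chosen only after the result was seen. If reads of the parent gene Rpl34 were given to it, Rpl34 would change, and its log2 fold change was 0.088 (SE 0.12). A different handling of pseudogenes in these libraries would move others, and the median of 67 was 0.145, so a general change of that kind lacks the value it needs. A chromosome segment from another strain would add called genes near it, and 9 of 44 genes within 5 Mb (20.5%) were called against 1557 of 12255 elsewhere (12.7%, Fisher exact p = 0.168), which leaves it open. Genotype and disease cannot be told apart here.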

How the results depend on the processing

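Rescaling each table by median-of-ratios moved the counts of called genes by the gate to 783 after cuprizone (1313 as TPM), 654 in 5xFAD (1023), and 2240 in the P28 stroke (4154). Against the references it moved them to 1368 for cuprizone GFP-positive cells (2338), 1847 and 2342 for EAE GFP-negative and GFP-positive cells (4099 and 4025), 899 and 2599 for those of 5xFAD (1591 and 5017), 19 and 148 for the P6 stroke (36 and 409), and 21 and 3076 for the P28 stroke (34 and 5150). By construction the rescaling sets the typical gene to no change. Why the counts moved was not tested.

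With the replicate block, the replicate number of the labels in the fit, the gate called 726 genes after cuprizone, 13 in EAE and 132 in the P6 stroke. Against the references the counts were 0 and 1167 for cuprizone, 1562 for EAE GFP-negative cells, 11 and 47 for the P6 stroke, and 0 for P28 GFP-negative cells. In the 2 fits with 0 calls 816 and 1433 genes had an unadjusted limma p under 0.05. The wild type controls are other mice, so there the block cannot test pairing. For other libraries, whether equal numbers mark the same animal is not given. In the P6 stroke equal numbers had the same sex in all groups, as the same animal would. The main fits take all libraries as independent. In no contrast did all libraries of equal number correlate above 0.1, and each library went best with its own number only for P6 GFP-negative and contralateral cells, 4 of 4. The cause was not tested.

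A robust variance without trend gave 608 genes after cuprizone, 23 in EAE, 616 in 5xFAD and 138 in the P6 stroke by the gate. Against the references it gave 6 for cuprizone GFP-negative cells, 1048 for those of 5xFAD, 18 and 76 for the P6 stroke, and 6 for P28 GFP-negative cells. The cause was not tested. Without a filter on low values the gate called 550 genes in glioma, 57 in EAE and 49 in the P6 stroke, and the references 5 for cuprizone and 3 for P28 GFP-negative cells and 113 for P6 GFP-positive cells. The cause was not tested.

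Fits of only the 2 groups compared called 406 genes in glioma, 35 in EAE and 70 in the P6 stroke by the gate. They called 3 for cuprizone GFP-negative cells, 2493 for EAE GFP-negative cells, 71 for P6 GFP-positive cells and 2 for P28 GFP-negative cells against the references. The cause was not tested. A pseudocount of 0.1 gave 13 genes for cuprizone GFP-negative cells and 59 for the gate in EAE, and the cause was not tested.

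Asking for a 2-fold change leaves fewer genes by construction. By the gate there were 522 after cuprizone, 412 in glioma, 45 in EAE, 441 in 5xFAD, 142 in the P6 and 891 in the P28 stroke. The same minimum left 978 for cuprizone GFP-positive cells, 3847 and 5777 for glioma, 2206 and 2171 for EAE, 686 and 3204 for 5xFAD, 17 and 95 for the P6 stroke, and 1332 for P28 GFP-positive cells. It left 1304 genes for the difference between models and 462 for that between the strokes. With cuprizone controls of the same sex, an alternative added after the data were seen, GFP-positive cells had 1519 genes, with 2 controls in place of 4.

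The 11 shared genes became 6 with a pseudocount of 0.1, 2 without a filter, 10 at a TPM of at least 5, 7 with rescaled values (5 of the 11, with Clec7a and Pkm new), 7 with the replicate block (Gpnmb, Igf1 and Spp1 of the 11, with Clec7a, Lpl, P2ry12 and Selplg new) and 4 with a 2-fold minimum. Gpnmb and Igf1 stayed in every setting. The cause was not tested.

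With 1 library left out, the gate called 771 to 1079 genes after cuprizone, 420 to 1025 in glioma, 25 to 211 in EAE, 637 to 867 in 5xFAD, 22 to 1292 in the P6 and 3182 to 4607 in the P28 stroke. GFP-negative cells against their reference gave 3 to 30, 6858 to 7551, 2168 to 4773, 999 to 1624, 3 to 27 and 2 to 46 in the same order. GFP-positive cells gave 1555 to 1972, 8488 to 8925, 2734 to 2941, 4444 to 5009, 53 to 1195 and 4223 to 5428. The difference between the strokes gave 900 to 1653.

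Some changes turned their sign with rescaled values, and of these H2-DMb1 (limma adjusted p = 0.0279) and Ighm (0.0492) in 5xFAD GFP-positive cells are called there in the other direction. In EAE GFP-negative cells against controls they became 0.0198 for Ndufv1, 0.008848 for Hspa5, 0.0345 for Pdia6 and 0.147 for Trf. In 5xFAD GFP-positive cells against controls they became 0.09361 for Cd86, 0.308 for H2-DMb1, 0.0948 for P4ha1, 0.05869 for Uqcrc1, 0.0549 for Atf4, 0.326 for Ighm and 0.0331 for Slc1a3. By the gate in the P28 stroke they became 0.0281 for Cd86, 0.00247 for P4ha1 and 0.0135 for Xbp1, and against the contralateral side 0.0772 for Ighm and 0.00642 for Trf. By construction rescaling shifts the well expressed genes of a contrast by about the same amount.

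Of 522 pairs of list and contrast 307 were called, and 184 with an estimated correlation. It was 275 with fry, 316 with rescaled values and 310 with a pseudocount of 0.1. With fry the iron and redox list turned by the gate in 5xFAD (fry adjusted p = 0.546) and phagocytic receptors with complement in 5xFAD GFP-positive cells against controls (fry adjusted p = 0.0389), and the cause of these differences was not tested.

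Of the 235 calls of named genes, a gene counted in each contrast that names it, 211 stayed with a pseudocount of 0.1, 187 without a filter, 226 of 226 at a TPM of at least 5, 224 with rescaled values, 195 with only 2 groups, 192 with the replicate block, 199 with a robust variance without trend and 178 whichever library was left out. Of the added alternatives, leaving out genes of at least 1% of TPM kept 92 of 95, a term for sex 56 of 60 and controls of the same sex 18 of 20. None of these turned its sign.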

Other observations

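By Xist and the Y genes, the 5xFAD table is female throughout, the glioma, EAE and P28 tables are male, and in the P6 table libraries 1 and 2 of each group are male and 3 and 4 female.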
